A study of Homo sapiens with 9 samples.

How the data were processed

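H3K27ac HiChIP, an assay that ligates DNA ends lying close together in fixed nuclei and enriches the products with an antibody against an acetylated histone mark of active promoters and enhancers, was carried out in 4 PANC-1 libraries and 5 EndoC-bH1 libraries. PANC-1 is a cell line from a pancreatic ductal adenocarcinoma, and EndoC-bH1 is a human beta cell line made from fetal pancreas. The data used here were 1 deposited loop list per cell line, with no column per library. Each line is therefore a single value for every quantity, no difference between the lines could be set against a spread between replicates, and no p-value is given. The build was hg38, per the submitters' processing notes. The aligner, the loop caller, its thresholds and the way the libraries were combined are not given in the sources used here.

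Each row of the lists holds the positions of the loop's 2 anchors, a whole-number count, a significance value and the name of the cell line. The deposited count per loop is not normalized, and was read as the number of read pairs joining the anchors. The deposited p-value or q-value per loop (which of the 2 it is was not stated) lies below 0.01 in both lists and is exactly 0 for 40.8% of PANC-1 loops and 34.8% of EndoC-bH1 loops. In the values themselves, anchors of a list do not overlap each other, and anchor midpoints lie between 5 kb and 1998 kb apart. A gene or region without a loop is one for which the list holds none; weaker contacts below the authors' threshold are not visible. Summed counts were 4180339 in PANC-1 and 1313860 in EndoC-bH1; they cover called loops only and are not the sequencing depth, which is unknown here.

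Positions are given 1-based. Loops were ranked within a list by the significance value, with ties broken by the higher count. A loop was called shared when its 2 anchors overlapped, by at least 1 bp each, the 2 anchors of a loop in the other list. Chance overlap was described by moving the EndoC-bH1 loops along their chromosomes by a random distance, wrapping at the end, in 100 draws. Gene positions came from a RefSeq gene table of assembly GRCh38.p14, the same build. The table holds neither strand nor transcript starts, so the promoter window planned before the data were examined was applied to both ends of each gene: a loop was assigned to a protein-coding gene when either end of the gene lay within 1 kb of an anchor. Such a gene is called looped. Part of these assignments are 3′ ends, and genes that share an anchor share its loops: 23.1% of gene-end anchors in PANC-1 and 24.2% in EndoC-bH1 touched several genes.

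Loop numbers per gene were scaled by the number of loops with a gene end in each list (112530 and 39560) and compared as log2 ratios of PANC-1 over EndoC-bH1 with a pseudocount of 0.5 scaled loops, which understates the change of genes with few loops. The median log2 ratio over the 14182 genes looped in either list was 0.33, and list medians should be read against it. For 12 gene lists fixed before the data were examined, the median over looped members was placed among 10000 random lists of the same size, matched in 20 bins on the mean scaled loop number; this percentile describes these 2 loop lists and is not a test across replicates. Of 357 list entries, 355 matched a current symbol, 1 an older symbol and 1 none. A ratio against 0 loops depends on the pseudocount, so loop numbers are printed for such genes, and each list's median is also given with 0 loops set to 3 loops. These 3 loops are unscaled and equal 2.03 scaled loops in PANC-1 and 5.77 in EndoC-bH1. A gene looped in a single line was given a ratio of 0 when its scaled loops fell below the other line's value. The setting therefore shrinks ratios towards PANC-1 more than those towards EndoC-bH1, and a list median of 0 can come from it alone. Intervals for shares are 95% Wilson intervals, and those for ratios of loop numbers are exact 95% intervals; both cover counting error only and treat loops as independent, which loops that share anchors are not. Intervals around list medians are from 2000 bootstrap draws of the members.

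The genes named were set by a rule written before the data were examined: up to 4 members of each list with the largest absolute log2 ratio among those with at least 5 loops in both lists together; INS, PDX1, KRT19 and SOX9; the 8 genes with most loops in each list; the 8 with the largest ratio in each direction among genes with at least 10 loops; and the 5 best-ranked shared and unshared gene-end loops of each list. Not every gene or loop picked by this rule is printed. Other names were chosen after their values were seen, as examples of their list or region. The alternatives were the overlap rule, the gene window, genes of all types, the better-ranked 50% of each list, PANC-1 lists shortened by rank or at random to the EndoC-bH1 length, a minimum span of 20 kb, the pseudocount, the minimum number of loops and scaling per chromosome. Added after seeing the data were the removal of a block on chromosome 19, whole genes in place of gene ends, counts in place of loops, and the setting of 0 loops to 3. Transcript starts could not be tried, and leaving out libraries was not possible.

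The overlap and gene-list steps were tested on simulated data. All of 5000 jittered EndoC-bH1 loops were recovered as shared (100.0%) and none of 20000 loops placed on unused sequence. Both anchors of a loop were jittered together by less than a typical anchor width, and the unused positions lay beyond all anchors of chromosome 1. These results therefore check the code only and say nothing about false sharing among dense anchors. The first form of the gene-list test used 1 simulated list of 25 genes with at least 3 scaled loops per log2 ratio and missed its limits, and the test was then eased to at least 10 scaled loops and to 100 genes, where true log2 ratios of 1 and 2 gave 1.04 and 1.91. All forms were therefore simulated 200 times. With 25 genes of at least 3 scaled loops, a size near that of the lists used here, the middle 95% of medians ran from -0.29 to 0.40 for unchanged genes, from 0.68 to 1.44 for a true value of 1 and from 1.63 to 2.53 for 2. With 100 genes of at least 10 scaled loops, it ran from 0.88 to 1.15 for 1. List medians therefore carry an error of at least this order from counting alone. The simulated genes were drawn independently, and looped members with under 3 scaled loops, which the real lists hold, were left out. The real error can be larger. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.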

Results

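To ask how far enhancer-promoter proximity depends on cell type, H3K27ac HiChIP loops were compared between PANC-1, a ductal adenocarcinoma line, and EndoC-bH1, a beta cell line. The PANC-1 list, from a line with 4 libraries, held 163751 loops between 79102 anchors, and the EndoC-bH1 list, from a line with 5 libraries, held 65049 loops between 46728 anchors. PANC-1 thus had 2.52 times as many loops and 1.69 times as many anchors. Counts per loop were similar, with a median of 15 (interquartile range 9 to 26) in PANC-1 and 14 (9 to 23) in EndoC-bH1. Summed over loops the counts came to 4180339 and 1313860, a ratio of 3.18. Because there was 1 list per line, none of the differences below has a replicate check.

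Most loops in both lines touched the end of a protein-coding gene, and those in PANC-1 did so more often. A gene end lay at both anchors of 15.2% of PANC-1 loops (95% Wilson interval 15.0 to 15.4) and 14.8% of EndoC-bH1 loops (14.5 to 15.0). A gene end at a single anchor was found for 53.5% of PANC-1 loops and 46.1% of EndoC-bH1 loops, and no gene end for 31.3% and 39.2%. PANC-1 loops were longer, with a median span of 74.1 kb (interquartile range 27.1 to 183 kb) against 53.9 kb (20.6 to 146 kb). Anchors in PANC-1 carried a mean of 4.14 loops and those in EndoC-bH1 a mean of 2.78.

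In all, 34.1% of EndoC-bH1 loops (22204 loops, 95% Wilson interval 33.8 to 34.5%) had a counterpart in PANC-1, and 13.7% of PANC-1 loops (22426 loops, 13.5 to 13.9%) had one in EndoC-bH1. After the EndoC-bH1 loops were moved along their chromosomes, a median of 2.36% matched a PANC-1 loop, and the highest of 100 draws gave 2.84%. Moving the loops also takes their anchors off regions that carry anchors in both lists. The contrast therefore does not separate common anchors from common pairing of anchors. Loops between gene ends were shared most: 65.2% of EndoC-bH1 loops with gene ends at both anchors were in the PANC-1 list, against 41.1% of those with a gene end at a single anchor and 14.2% of those with none. The same order held in PANC-1, where the shares were 25.8%, 14.2% and 6.89%. Shared loops were shorter. Their median span was 42.5 kb in EndoC-bH1 against 61.3 kb for unshared loops, and 42.1 kb in PANC-1 against 81.0 kb. The level of sharing depended on the overlap rule and on the length of the PANC-1 list: the EndoC-bH1 share was 46.1% with anchors extended by 5 kb, 18.6% when anchors had to overlap by 50%, and 20.5% or 14.2% with the PANC-1 list cut to the EndoC-bH1 length by rank or at random. The PANC-1 share was 24.7% with extended anchors and 7.40% with overlap of 50%.

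**Figure D1:**
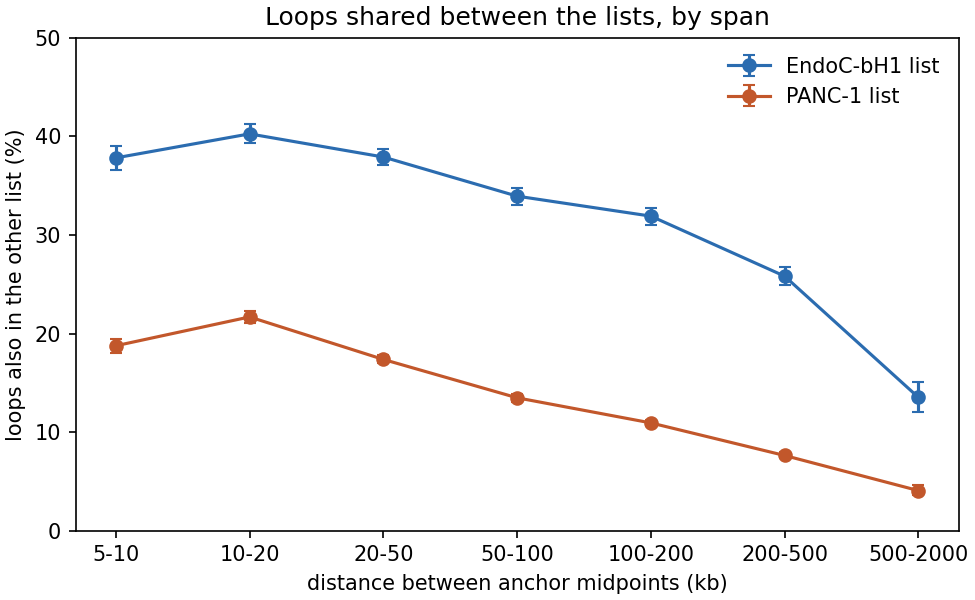
Share of each list's loops that are also in the other list (y axis, percent) by the distance between anchor midpoints (x axis, kb); points are the 2 lists and bars are 95% Wilson intervals, which cover counting error only. In EndoC-bH1 the share is highest at 10 to 20 kb (40.3%) and lowest at 500 to 2000 kb (13.5%), and in PANC-1 it goes from 21.7% to 4.08%.

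A loop can be shared only where both its anchors are present in the other list. Of the EndoC-bH1 anchors, 53.0% overlapped a PANC-1 anchor. Both anchors were present in PANC-1 for 50.4% of EndoC-bH1 loops, and 67.7% of these were also PANC-1 loops. For 24.3% of EndoC-bH1 loops a single anchor was present in PANC-1, and for 25.3% neither was. In the other direction, both anchors of 32.1% of PANC-1 loops were present in EndoC-bH1, and 42.7% of these loops were shared. An anchor is in a list only because it carries a called loop, so each shared loop makes its own anchors present. The shares of 67.7% and 42.7% are raised by this, and regions with the mark but without a loop are left out. The best-ranked loops were shared most, without a steady trend below them: from the best-ranked to the last 25% of the list the shares were 41.4%, 31.2%, 34.0% and 30.0% in EndoC-bH1 and 24.9%, 10.6%, 10.7% and 8.58% in PANC-1. All of the best-ranked 25% had a significance value of 0, so their order follows the count. Counts fell with span across loops (Spearman -0.59 in PANC-1 and -0.58 in EndoC-bH1), and the effect of rank on sharing was not separated from that of span. Across the 22204 shared EndoC-bH1 loops, counts had a Spearman correlation of 0.44 with those of each loop's best-ranked PANC-1 partner. This value is across loops and not across replicates, and the part that follows from span was not separated.

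The best-ranked shared gene-end loops were short, with spans between 7.60 and 18.0 kb, but a ranking that follows the count favours short loops. The first lay on chromosome 19 between MED29, a Mediator subunit gene, at 39400888 to 39403716 and PLEKHG2 and ZFP36 at 39406291 to 39414384 (EndoC-bH1 anchors, hg38), with a count of 296 in EndoC-bH1 and 20806 in PANC-1. Others joined an anchor at BCL9L to one without a gene end (counts 180 and 1857) and the MUC1, THBS3 and TRIM46 anchor to the MTX1 and THBS3 anchor on chromosome 1 (190 and 442). The best-ranked unshared EndoC-bH1 loops included 3 at transcription factor genes. FOXP2, a forkhead factor gene, was joined to an anchor 331 kb away on chromosome 7 (114081568 to 114088999 and 114411817 to 114421379; count 380). NKX2-2, an islet transcription factor gene, was joined to an anchor at 21562964 to 21566475 on chromosome 20 (count 373). CRYBA2 to CFAP65, the factor gene MYT1 and the desmosome gene DSP had counts of 315 each. The best-ranked unshared PANC-1 loops lay at ACTN4 (count 3293), MED29 to PLEKHG2 and RPS16 (3212), and PSMC4 (2829 and 2534) on chromosome 19. These loops and the first shared loop lie in the chromosome 19 block described below, where extra DNA copies could raise counts. Another joined FOSL1, an AP-1 subunit gene, to C11orf68 and DRAP1 on chromosome 11 (65897579 to 65904872 and 65908113 to 65921694, count 2544).

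Most genes looped in EndoC-bH1 were also looped in PANC-1. Of 20037 protein-coding genes, 12651 were looped in PANC-1 and 10318 in EndoC-bH1, and 8787 were looped in both, against 6515 for independent sets of these sizes. Thus 85.2% of EndoC-bH1 looped genes were also looped in PANC-1. Genes looped in PANC-1 alone numbered 3864, those in EndoC-bH1 alone 1531, and 5855 were looped in neither. The balance of the single-line groups depended on how the PANC-1 list was cut to the EndoC-bH1 length: cut by rank, 2298 genes were looped in PANC-1 alone and 3120 in EndoC-bH1 alone, and thinned at random, 2881 and 2482. A looped gene had a median of 7 loops in PANC-1 and 3 in EndoC-bH1.

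Genes of beta cell identity were looped in EndoC-bH1 and mostly not in PANC-1. Of 24 endocrine transcription factor genes, 21 were looped in EndoC-bH1 and 6 in PANC-1, and the median log2 ratio of PANC-1 over EndoC-bH1 was -4.82 (bootstrap interval -6.56 to -4.44), below every one of the 10000 random lists. NKX2-2 (chromosome 20, 21511017 to 21522689) had 81 loops in EndoC-bH1 and 0 in PANC-1. INSM1, a zinc finger factor gene of endocrine cells, had 40 and 0. PDX1, the pancreatic master regulator (chromosome 13, 27920000 to 27926313), had 37 loops in EndoC-bH1 and 3 in PANC-1. FOXA2, a factor of the whole foregut endoderm, was looped in both lines, with 67 loops in EndoC-bH1, 52 of them shared, and 76 in PANC-1, a scaled log2 ratio of -1.32 (exact interval -1.82 to -0.83). Only ETV1, with 3 loops in EndoC-bH1 and 26 in PANC-1, had more scaled loops in PANC-1. Setting 0 loops to 3 gave a median of -4.51.

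The secretory genes of beta cells went the same way. Of 32 genes, 30 were looped in EndoC-bH1 and 6 in PANC-1, all 30 had more scaled loops in EndoC-bH1, and the median log2 ratio was -4.03 (-4.46 to -3.71), again below all random lists; with 0 loops set to 3 it was -2.38. INS, the insulin gene (chromosome 11, 2159779 to 2161209), whose anchors also touch the readthrough gene INS-IGF2, had 7 loops in EndoC-bH1 and 0 in PANC-1. The prohormone convertase genes PCSK2 and PCSK1 had 22 and 19 loops in EndoC-bH1, the granule protein gene CHGA 20 and the potassium channel gene KCNJ11 11, and each had 0 in PANC-1. Of the 226 loops at these genes in EndoC-bH1, counted per gene, 2.65% were shared. Genes of neuronal exocytosis, many of which beta cells also use, had a median of -2.28 (-4.59 to -2.01), at the 0.005 percentile, with 18 of 20 looped members higher in EndoC-bH1, and of -2.41 with 0 loops set to 3. RIMBP2 had 23 loops in EndoC-bH1, RIMS2 and SCN3B 9 each and KCNK16 8, against 0 in PANC-1; SCN3B shares anchors with GRAMD1B and KCNK16 with KCNK17.

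**Figure D2:**
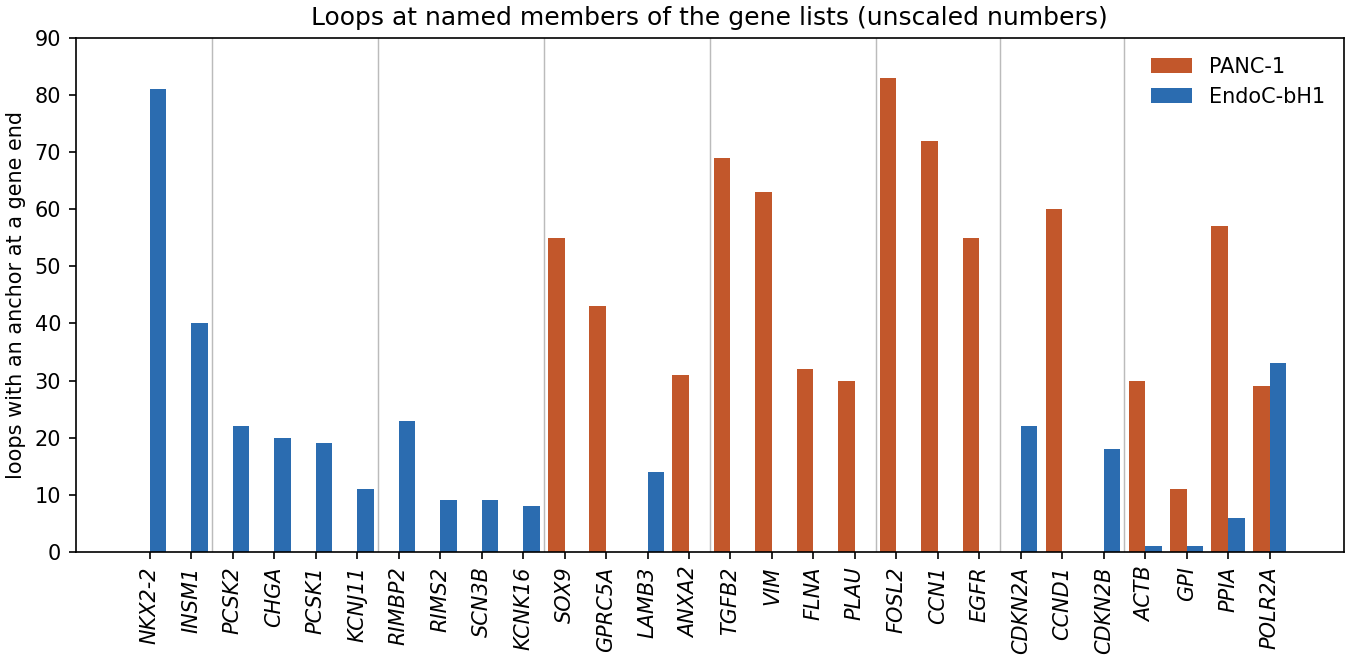
Number of loops with an anchor at a gene end (y axis, unscaled) for the named members of 8 gene lists (x axis; grey lines part the lists, in the order endocrine transcription factors, beta cell secretion, neuronal exocytosis, duct and epithelium, mesenchyme, YAP, TEAD and AP-1, growth and PDAC drivers, housekeeping). NKX2-2 to KCNK16 have bars in EndoC-bH1 alone, from 81 loops down to 8, and FOSL2, CCN1 and TGFB2 have bars in PANC-1 alone, with 83, 72 and 69.

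Genes of the YAP, TEAD and AP-1 programme, active in spread and mesenchymal cells, were looped in PANC-1. Of 34 genes, 30 were looped in PANC-1 and 14 in EndoC-bH1, the median log2 ratio was 2.34 (1.69 to 4.94), above all random lists, and 26 of 31 looped members had more scaled loops in PANC-1. With 0 loops set to 3 the median was 1.37. FOSL2 had 83 loops in PANC-1, CCN1 (CYR61), a classical YAP target whose anchors also touch DDAH1, 72, TGFB2 69 and EGFR 55, all against 0 in EndoC-bH1. FOSL1, whose anchors also touch CCDC85B and FIBP, had 150 and 5, and JUN 57 and 4. YAP1, WWTR1 and TEAD4 had 30, 22 and 22 loops in PANC-1 and 0 in EndoC-bH1. Mesenchymal genes had a median of 1.89 (1.10 to 2.96; 99.8th percentile), but 11 of 33 were looped in neither line. The median was 0.30 with 0 loops set to 3, and with whole genes in place of gene ends it was 1.25 and lay within the random range (92.6th percentile). VIM, the vimentin gene, had 63 loops, FLNA 32 and PLAU 30 in PANC-1, each with 0 in EndoC-bH1, and ZEB1 had 34 and 3. The 0 of FLNA depended on the window: with gene ends within 2.5 kb it had 36 loops in PANC-1 and 3 in EndoC-bH1. FN1, CDH2, SNAI2 and TWIST1 were looped in neither.

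Duct and epithelial genes did not stand apart as a list. Their median log2 ratio was 0.87 (-0.62 to 1.95; 93.9th percentile), with 13 looped members higher in PANC-1 and 10 in EndoC-bH1; it was 0 with 0 loops set to 3 and -0.19 for whole genes. SOX9, a duct progenitor factor gene (chromosome 17, 72121020 to 72126416), had 55 loops in PANC-1 and 0 in EndoC-bH1, GPRC5A 43 and 0, and ANXA2 31 and 0. KRT19, a duct keratin gene (chromosome 17, 41523617 to 41528308) that shares anchors with KRT15, had 112 and 10, a log2 ratio of 1.95 (exact interval 1.04 to 3.08). LAMB3 went the other way with 14 loops in EndoC-bH1 and 0 in PANC-1, as did TFF1 with 14 and 1. Exact intervals of the ratio lay above 0 for 6 members of the list and below 0 for 6. KRT8, CLDN4 and ELF3, which share anchors with KRT18, METTL27 and RNPEP, were looped in both lines. They had 38 and 18, 29 and 26, and 33 and 18 loops in PANC-1 and EndoC-bH1. After scaling all of them were higher in EndoC-bH1, with log2 ratios of -0.42, -1.33 and -0.62, and only the interval of CLDN4 left out 0. CFTR, CA2 and AQP1 were looped in neither line. The growth and PDAC driver list also lay within the random range (0.67, 88.4th percentile; 0.24 with 0 loops set to 3). CCND1, which shares anchors with LOC124902704, had 60 loops and MYC 48 in PANC-1 against 0 in EndoC-bH1, while the tumour suppressor genes CDKN2A and CDKN2B had 22 and 18 in EndoC-bH1 against 0 in PANC-1. These last genes lie in a stretch without any PANC-1 anchor, described below, where missing loops cannot be told from missing DNA.

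Marker genes of other cell types were often without loops, and some had many. Acinar markers were looped for 11 of 27 genes in PANC-1 and 6 in EndoC-bH1, with a median of 1.89 (-1.04 to 2.96; 91.9th percentile) that had no stable direction: it was 0 with 0 loops set to 3, -0.63 with gene ends within 2.5 kb, -0.15 with the PANC-1 list shortened by rank, and 2.65, above the random range, among members with at least 3 loops. CELA3B had 32 loops, SYCN, which lies in the chromosome 19 block described below and shares anchors with NCCRP1, 25 (39 and 1 in EndoC-bH1 with gene ends within 2.5 kb), and CTRC 5 in PANC-1 with 0 in EndoC-bH1, and CPA1 had 23 in EndoC-bH1 and 1 in PANC-1. Markers of other islet cells had a median of -2.35 (-3.12 to -0.49; 0.045th percentile), which was -0.39 and within the random range among members with at least 3 loops and -0.92 with 0 loops set to 3. CRYBA2 had 16 loops and PCSK1N, which shares anchors with ERAS, 10 in EndoC-bH1, against 0 and 1 in PANC-1, PLCE1 had 29 and HHEX 6 in PANC-1 against 0, and GCG and SST were looped in neither. Endothelial and immune markers had a median of -0.26 (-0.93 to 1.23; 10.3rd percentile), -0.09 with 0 loops set to 3 and 0.85 for whole genes. TYROBP, whose anchors also touch HCST, had 8 loops in PANC-1 and 0 in EndoC-bH1, TIE1 3 and 5, and SPI1 3 and 2, while the macrophage gene CD68, whose anchors also touch EIF4A1 and MPDU1, had 31 of the list's 73 loops in PANC-1 and 14 of its 33 in EndoC-bH1, and PTPRC, PECAM1 and CDH5 were looped in neither.

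Housekeeping genes were looped in both lines. All 30 were looped in PANC-1 and 28 in EndoC-bH1, and the median log2 ratio was 0.33 (0.06 to 0.61; 86.2nd percentile; 0.21 with 0 loops set to 3), against a median of -0.10 for the matched random lists. Of the loops at these genes, counted per gene, 77.2% in EndoC-bH1 and 27.0% in PANC-1 were shared. POLR2A, an RNA polymerase subunit gene whose anchors also touch SLC35G6 and ZBTB4, had 29 loops in PANC-1 and 33 in EndoC-bH1, ACTB 30 and 1, PPIA 57 and 6, and GPI, which shares an anchor with PDCD2L, 11 and 1. Genes tied to type 2 diabetes had a median of -1.13 (-3.12 to 1.89; 0.565th percentile; -0.99 with 0 loops set to 3), carried by members that are also in the islet lists: of the 28 genes found in no other list 16 were looped, with a median of 0.05 (24.2nd percentile). TCF7L2 had 49 loops and IGF2BP2 33 in PANC-1 against 0 in EndoC-bH1.

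**Figure D3:**
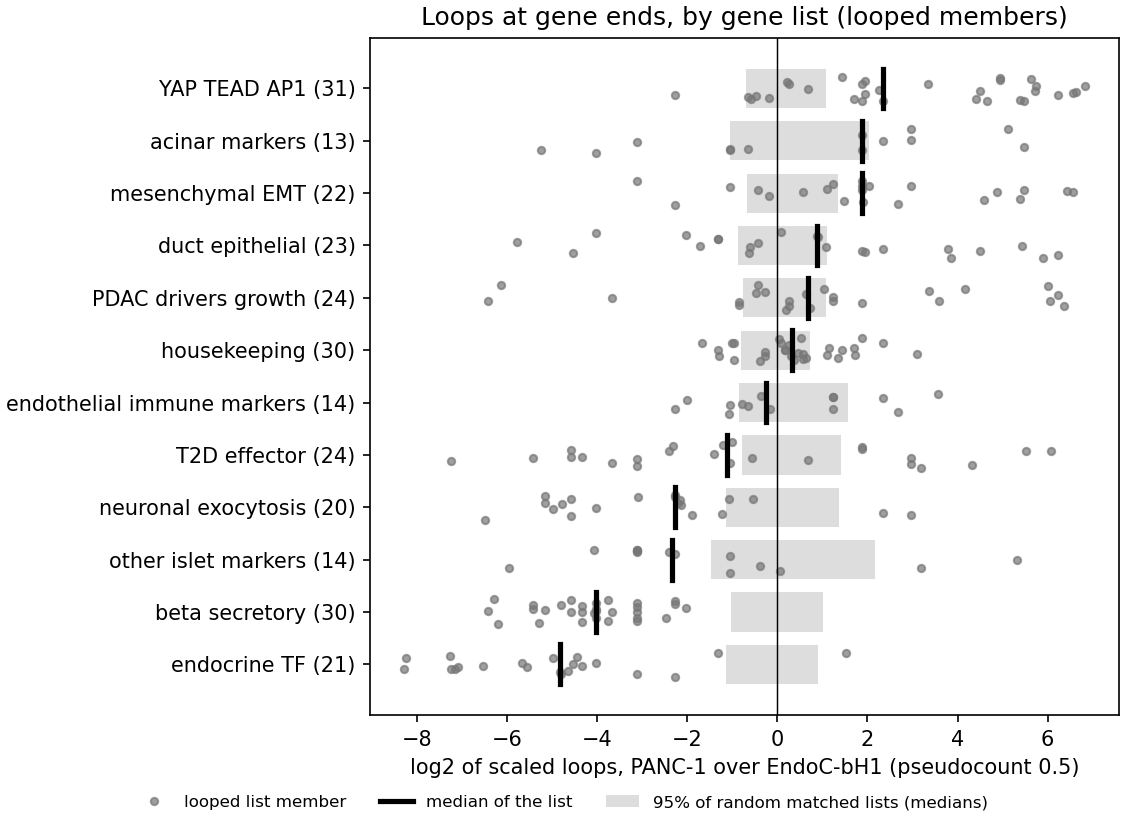
Log2 ratio of scaled loop numbers, PANC-1 over EndoC-bH1 (x axis, pseudocount 0.5), for the looped members of 12 gene lists (rows, number of looped members in brackets); grey points are genes, black bars list medians, and grey bands the middle 95% of medians of 10000 random lists matched on loop number. The endocrine transcription factor and beta cell secretion medians (-4.82 and -4.03) lie left of their bands and the YAP, TEAD and AP-1 median (2.34) right of its band.

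The genes with most loops differed between the lines. In EndoC-bH1 these included FOXP2 with 108 loops, ID2 with 107, ZNF608 with 85, MARCKS with 82, NKX2-2 with 81, ATP1B1 with 72 and STX16 with 68. In PANC-1, FOXP2 and NKX2-2 had 0 loops and ID2 17, while ZNF608 had 85, MARCKS 93, ATP1B1, which shares anchors with NME7, 71 and STX16 38. After scaling all of these were higher in EndoC-bH1. The largest ratios towards EndoC-bH1 included those of FOXP2, NKX2-2, RASGEF1B (56 loops), ZNF831 (55), MAF (53), CDK14 (50) and GLUL (49), each with 0 loops in PANC-1. The 8 genes with most loops in PANC-1 were neighbours on chromosome 19: PLEKHG2 (461 loops against 29 in EndoC-bH1), MED29 (459 and 14), RPS16 (451 and 2), SAMD4B (433 and 16), FBL (362 and 18), ACTN4 (360 and 14), DYRK1B (348 and 18) and PSMC4 (303 and 6). Several of these share anchors with each other. Of the 8 largest ratios towards PANC-1, 7 lay in the same stretch, at ZNF546 (195 loops), ZNF780A (179), LEUTX (178), ZNF780B (144), CCNP (137), MAP3K10 (114) and CLC (111), and the other was HOXB5 on chromosome 17 (125), all with 0 in EndoC-bH1. CCNP shares anchors with TTC9B, CLC with LGALS14 and HOXB5 with HOXB3 and HOXB6.

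The lines also differed in how loops were spread over chromosomes. Chromosome 19 held 10.6% of PANC-1 loops and 4.20% of EndoC-bH1 loops, a log2 ratio of 1.34, and chromosomes 10 and 18 followed with 0.90 and 0.80. Chromosome 13 had the lowest ratio, -1.21 (0.86% and 1.98% of loops), followed by chromosomes 4 (-1.16), 21 (-0.90), 20 and 14 (-0.89 each). Chromosome 20 held 3.54% of PANC-1 loops and 6.57% of EndoC-bH1 loops. NKX2-2, INSM1, FOXA2, PCSK2, STX16 and ZNF831 lie on chromosome 20, and their main ratios are not corrected for this. On chromosome 19 the 3 Mb from 38 to 41 Mb held 7274 PANC-1 loops, 4.44% of the list and 11.3% of its summed counts, against 330 EndoC-bH1 loops, 0.51% of the list. Without this block the ratio of chromosome 19 was 0.80, so that it remained above 0. In windows of 100 kb, PANC-1 had between 146 and 648 loops in each of the 18 windows from 38.5 to 40.3 Mb, and at most 65 in any other window of the block. All 56 protein-coding genes there were looped in PANC-1, AKT2 with 266 loops against 5, and 39 were looped in EndoC-bH1.

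**Figure D4:**
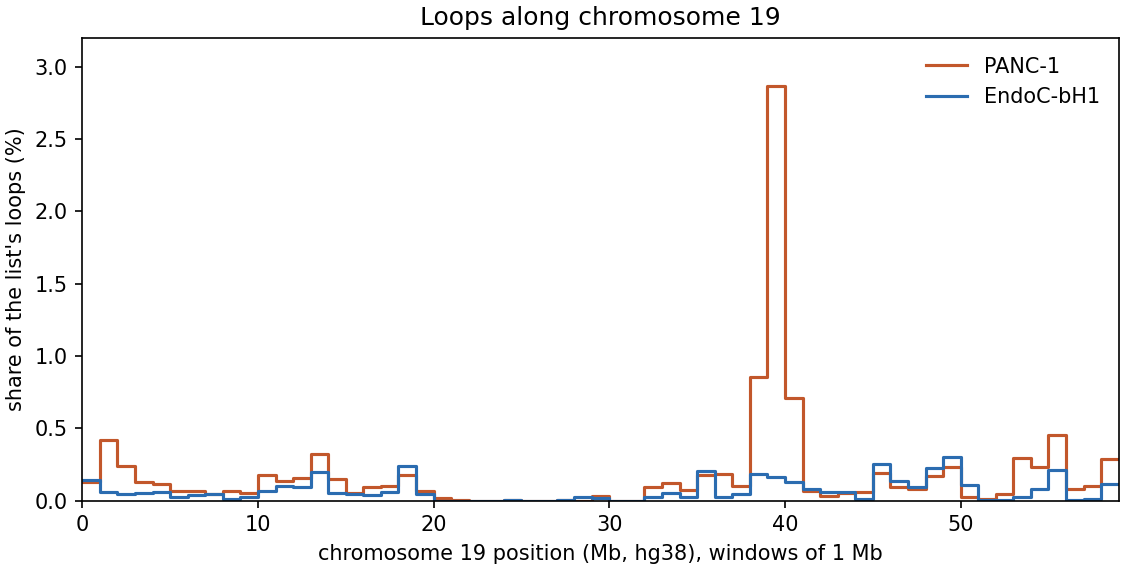
Share of each list's loops (y axis, percent) in windows of 1 Mb along chromosome 19 (x axis, hg38, by loop midpoint), 1 line per cell line and no error bars because there is 1 list per line. PANC-1 reaches 2.87% of its loops in the window from 39 to 40 Mb, where EndoC-bH1 has 0.16%.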

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

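No paired analysis was possible because the lists carry no column per library, so the shared replicate numbers could not be used, and no library could be left out; transcript starts were not tried for want of strand. With 1 list per line, a share, ratio or median was taken to have moved when it left its own 95% interval, and a count when it changed by over 1.5 times. The interval covers counting error, or for list medians comes from the bootstrap of the members. No called direction of a list median or ratio was reversed. With PANC-1 shortened by rank, however, genes looped in a single line became more numerous in EndoC-bH1 than in PANC-1. Among alternative values of the main results 131 stayed and 65 moved, and among the other values 624 stayed and 25 moved. Staying says little for list medians and for genes with 0 loops in a line, whose intervals are wide or open-ended. The acinar median counted as stayed although it went from 1.89 to -0.63 with gene ends within 2.5 kb. Removal of the chromosome 19 block, whole genes, counts and 0 loops set to 3 were chosen after the data were seen. The read-pair threshold and the sequencing depth limit what can be seen, since contacts that the lists do not hold cannot be told from absent ones. The cause of the changes below was not tested unless it follows from fewer loops or wider windows.

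The EndoC-bH1 and PANC-1 shares were 46.1% and 24.7% with anchors extended by 5 kb, 18.6% and 7.40% with overlap of 50%, 28.0% and 11.3% in the better-ranked 50%, and 20.5% and 19.4% with PANC-1 shortened by rank; thinned at random, the EndoC-bH1 share was 14.2%, and without the chromosome 19 block the PANC-1 share was 14.2%. Shared loops stayed shorter than unshared ones: with PANC-1 shortened by rank the medians were 34.4 and 106 kb in PANC-1 and 35.0 and 59.2 kb in EndoC-bH1, and with extended anchors the unshared medians were 88.8 and 66.3 kb. The difference in sharing between the best-ranked and last 25% of EndoC-bH1 went from 11.4 to 5.05 percentage points with extended anchors. The better-ranked 50% held 81875 and 32524 loops by construction.

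The share of loops with a gene end, in PANC-1 and EndoC-bH1, was 66.9% and 58.8% with the end inside the anchor, 71.2% and 63.6% within 2.5 kb, 70.7% and 62.0% in the better-ranked 50%, 80.1% and 73.8% for genes of all types and 91.2% and 87.9% for whole genes; gene ends at both anchors made up 12.9% and 12.9%, 18.7% and 17.9%, 18.6% and 16.8%, 25.1% and 24.0%, and 64.0% and 61.1%. Without the block the PANC-1 shares were 68.3% and 14.8%. With PANC-1 shortened by rank 2298 genes were looped in PANC-1 alone and 3120 in EndoC-bH1 alone, which reversed the balance. After thinning at random the numbers were 2881 and 2482, in the original direction. The ratios of chromosomes 13, 4, 21, 18, 10 and 19, the only ones computed again, kept their sign: loops of at least 20 kb gave -1.35 for chromosomes 13 and 4, 1.00 for 10 and 1.51 for 19; the better-ranked 50% gave -1.64, -1.61 and -1.06 for 13, 4 and 21 and 0.93, 1.06 and 1.76 for 18, 10 and 19; and 19 had 0.80 without the block. Among gene lists, beta cell secretion had -3.56 with PANC-1 shortened by rank, -3.35 with a pseudocount of 1, -4.61 for whole genes, -4.83 by counts and -2.38 with 0 loops set to 3, which also gave 0.30 for mesenchymal genes and 1.37 for YAP, TEAD and AP-1. Endocrine factors had -4.15 with a pseudocount of 1, endothelial and immune markers -0.97 with PANC-1 shortened by rank, and other islet markers -0.39 with at least 3 loops.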

Other observations

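The tests of the dense stretch and of the rest of the chromosome 19 block were chosen after the results were seen. The test of read pairs as the cause of the longer PANC-1 list was chosen after the overall share of shared loops, 34.1% in EndoC-bH1, had been seen. The other tests were set before their values were computed, though the block itself and this overall share were known by then. HOX genes, which set position along the body axis in development, were looked at after HOXB5 had appeared among the largest ratios, without a test, and their clusters differed. Of all protein-coding genes, 63.1% were looped in PANC-1 and 51.5% in EndoC-bH1. All 10 HOXB genes had loops in PANC-1, with a median of 83 per gene, and 1 of them (HOXB13, 2 loops) in EndoC-bH1. All 9 HOXC genes had loops in PANC-1 (median 79), and 5 had between 1 and 6 in EndoC-bH1. In the HOXA cluster 10 of 11 genes were looped in PANC-1 (median 5) and 0 in EndoC-bH1. The HOXD cluster was nearly empty, with 2 of 9 genes looped in PANC-1 and 1 in EndoC-bH1. HOX genes share anchors, so the same loop counts for several of them.

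Some windows of 1 Mb were full in a single line. The windows with the highest ratios towards PANC-1 were chromosome 12 from 75 Mb (528 loops and 0), chromosome 10 from 4 Mb (647 and 1), where no PANC-1 loop touched the end of a protein-coding gene lying in the window, and chromosome 8 from 127 Mb, which holds MYC (278 and 0). Those towards EndoC-bH1 were chromosome 16 from 78 Mb, which holds part of WWOX (0 and 185), chromosome 7 from 114 Mb with FOXP2 (3 and 166) and chromosome 8 from 29 Mb with DUSP4 (0 and 113). Around CDKN2A and CDKN2B on chromosome 9, PANC-1 had no anchor from 21815464 to 22344430, a stretch of 529 kb that held 27 EndoC-bH1 anchors and 70 EndoC-bH1 loops. Of the 79078 gaps between neighbouring PANC-1 anchors, 99 held at least as many EndoC-bH1 anchors. No DNA copy number was analysed, so missing loops in this stretch cannot be told from missing DNA. The highest count in EndoC-bH1, 1792, belonged to a loop without a gene end on chromosome 16 (46385644 to 46391460 and 46397704 to 46403245).

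The concentration of PANC-1 loops on chromosome 19 may come from extra DNA copies, which would raise all contacts there. Over the whole block from 38 to 41 Mb, 83.6% of 220 shared loops (95% Wilson interval 78.2 to 87.9%) had a PANC-1 to EndoC-bH1 count ratio above the median elsewhere, between the bounds set for and against this. The share was 97.5% of 160 shared loops (93.7 to 99.0%) in the stretch from 38.5 to 40.3 Mb and 45.6% (33.4 to 58.4%) in the rest of the block, but these parts were split by their number of PANC-1 loops, so the contrast between them decides nothing. As for a few anchors with very many loops, 80.8% of the block's 360 PANC-1 anchors (76.5 to 84.6%) had more loops than the 75th percentile of 3 elsewhere. This was above the bound set against that explanation. A few busy anchors joined to most of the block could lift the others above 3 loops, so this share alone cannot decide. An anchor joined only to a few busy ones could carry only a few loops, however, and the block's anchors had a median of 25. This argues against a few busy anchors as the source of the block's loops. Extra copies and a broad gain of activity both stay open, and no DNA copy number was analysed here.

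The PANC-1 list could be longer merely because more read pairs lay behind it. Of the best-ranked 25% of EndoC-bH1 loops, 41.4% recurred in PANC-1 (95% interval 40.7 to 42.2%). The test had taken a low value as evidence against read pairs as the whole cause, but recurrence shows where the lines loop and not why a list is longer, so that bound was wrong. Sequencing depth and the cell lines' own biology both stay open.

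A hypothesis drawn from the subject of the study is that pairs of regions that are close in the beta cell line are close in the ductal line as well, wherever both regions carry the mark. Among 19877 anchors that matched 1 to 1 between the lists, 668638 pairs lay within 2000 kb of each other. An anchor is in a list only because it carries a called loop, so the mark itself was not measured and marked regions without loops are left out. A pair looped in both lists can also bring in its own anchors, which raises the share among looped pairs. Of the 23044 pairs looped in EndoC-bH1, 70.8% were looped in PANC-1, against 3.39% of the other pairs; at 500 to 2000 kb the shares were 52.4% and 0.29%, and at 5 to 10 kb 80.3% and 28.8%. The span-matched ratio of the shares was 4.05 (3.98 to 4.21 leaving out each chromosome in turn), above the bound of 2 set beforehand against distance alone. That bound made no allowance for pairs that bring in their own anchors, so the ratio cannot exclude distance alone. With the loop numbers of both anchors in PANC-1 matched too, the ratio was 1.90 (1.89 to 1.93), between the bounds of 1.2 and 2, so that distance together with busy anchors could account for part of it and the hypothesis stays undecided. Matching on PANC-1 loop numbers also takes away some of any real recurrence, because the recurring loops are among those counted.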
